A study of Mus musculus with 6 samples.

How the data were processed

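The study measured RNA in mouse colon tissue by sequencing, in 3 samples from normal feeding and 3 samples from TNBS given into the colon. Groups and replicate numbers were taken from the submitters' sample labels. The labels present the replicates as separate colon samples and do not number the animals behind them, so p-values measure the spread between these samples. The tests treat the samples as independent, and whether TNBS replicate 3 is so stays open, as given below. Per the labels' protocols, total RNA was prepared with a GenSeq low input RNA kit and a SMARTER mRNA-Seq kit. Nothing in the sources used here says whether the libraries keep the strand. The submitters' processing notes name CASAVA 1.8, HISAT2 and the mouse build mm10. The counting tool, the version of HISAT2, the gene annotation and the filters are not given in the sources used here.

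The authors deposited 1 table with a whole-number read count per gene and library, per the file headers, and these counts are the values used here. It holds 16906 rows, each marked as protein-coding, so genes of other types were not analysed here. A second set of 6 columns with the same names, holding normalized values, was not used. Counts of a whole tissue move with the mix of its cells as well as with transcription, and a gene that takes many counts lowers the share of the others. Genes were identified by their Ensembl identifiers; 16732 of these carry a symbol in GENCODE vM21, whose build GRCm38 corresponds to mm10, and 174 do not. For 833 rows the symbol in the table differs from that of vM21, and the vM21 symbol is printed (for example Chil3, Ackr1 and Clca1). Coordinates are 1-based and come from vM21. Totals ran from 15185569 to 23380492 counts per library, where 3 counts correspond to 0.128 to 0.198 CPM. All intervals on counts cover counting error only.

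Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 14126, and scaled with TMM. The main comparison, TNBS against normal, was an edgeR quasi-likelihood fit with group as its only term (glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. CPM are TMM-scaled and given as mean ± SD over n = 3 libraries. For genes with 1 to 3 counts in a group, the ratio of scaled count sums is given with an exact 95% conditional binomial interval.

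Before the data were examined, 35 gene lists, the tests and the rule for named genes were fixed. The lists cover m6A machinery, cytokines, chemokines, neutrophils, monocytes and macrophages, T and NK cells, B and plasma cells, mast cells and eosinophils, epithelial antimicrobial genes, the interferon response, NF-kB and inflammasome, extracellular matrix, fibroblasts, absorptive colonocytes, goblet cells, enteroendocrine and tuft cells, stem cells and proliferation, epithelial junctions, fatty acid oxidation, oxidative phosphorylation, xenobiotic and bile metabolism, hypoxia and glycolysis, the unfolded protein response, oxidative stress and ferroptosis, smooth muscle, enteric neurons and glia, endothelium, fat and mesothelium, squamous anal epithelium, skeletal muscle, erythroid cells, immediate early genes, mitochondrially encoded genes, ribosomal proteins and the circadian clock. List members absent from the table were not analysed here. Named genes were the 8 with the largest and the 8 with the smallest log2 fold change among called genes whose groups did not overlap and whose mean was at least 50 counts in the higher group, leaving out genes without a symbol, pseudogenes and immunoglobulin or T cell receptor segments; Fto and any other called m6A gene; and from each list up to 3 called members with the smallest p or, where none was called, the 1 furthest from 0. A gene that the rule names is not reported here. Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and also with an estimated correlation and with fry. With the preset correlation 10 lists were called higher and 6 lower; with an estimated correlation none held (2 higher and 1 lower at an unadjusted p under 0.05), and fry called 4 higher and 3 lower. Enrichment used the pathway and process annotations that the table carries, for terms of 10 to 500 tested genes, with a one-sided hypergeometric test against all tested genes that have an annotation of that kind.

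The shared sequence of a named gene is the percent of the 50-base stretches of its vM21 transcripts that also occur in a transcript of another gene. Ccna2, Foxp3, Igf2bp3, Serpina3m, Synm and Ackr1 overlap other genes of the table in vM21, so their counts are uncertain where counting took no account of strand or of overlaps. The same steps were tested on simulated data with the means, library sizes and spread of the real libraries, 200 genes changed and 13834 genes in the fit: for TNBS against normal, 14.6% of genes changed 2-fold and 67.4% of those changed 4-fold were called in the right direction, with 2 calls among unchanged genes. A single change of 2-fold is therefore often missed at this depth and replicate number.

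Alternatives fixed in advance were no filter, a mean count of at least 50, median-of-ratios scaling, quantile normalization, limma-voom, DESeq2, limma-voom with quality weights, the replicate number as a block, leaving out each library in turn and a 2-fold minimum. Further fits were added after the data were seen: a correction for transcript length and GC content (loess with a span of 0.5 within each library, for the 99.5% of tested genes with a value), the same without TNBS replicate 1, and fits without the TNBS libraries low in Y-linked transcripts or without those whose Hox transcripts lay apart.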

Results

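RNA was sequenced from 6 samples of mouse colon tissue, 3 from normal feeding and 3 with colitis induced by trinitrobenzenesulfonic acid (TNBS). This hapten provokes an acute inflammation of the colon wall and is used as a model of Crohn's disease. The labels describe all donors as C57BL/6J males aged 6 to 8 weeks and weighing 20 to 22 g, and the TNBS was given into the colon at 5% w/v. The normal libraries held 22999588, 23380492 and 21624206 counts in protein-coding genes and the TNBS libraries 20537026, 15185569 and 18381576. The 10 most abundant genes took 5.80% to 11.1% of the counts of a library. Libraries of the same group differed by far more than counting error, with a chi-square per degree of freedom of 37.9 to 176, so no library was a copy of another. The first principal component of log2 CPM, the counts scaled to library size, held 50.7% of the variance and the second 22.7%.

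The TNBS libraries were not alike in 3 respects that bear on every comparison below. Transcripts of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, summed, stood at 0.697% of the normal mean in TNBS replicate 1, 103% in TNBS replicate 2 and 38.2% in TNBS replicate 3, against 92.1% to 114% in the normal libraries. Hoxb6, a member of the Hox family that marks position along the body axis, was at 3.36, 3.72 and 11.5 CPM in the normal libraries and at 8.95 in TNBS replicate 1, but at 79.3 and 80.6 in TNBS replicates 2 and 3. Hoxb13, expressed towards the hind end of the gut, was at 106, 57.7 and 7.37 CPM in the normal libraries, 21.4 in TNBS replicate 1, and 0.194 and 0.308 in TNBS replicates 2 and 3. Mitochondrially encoded genes took 0.563% to 0.951% of the counts of the normal libraries, 0.755% in TNBS replicate 1, 3.92% in TNBS replicate 2 and 1.95% in TNBS replicate 3.

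The design holds a single comparison, TNBS-treated against normal colon, which asks which transcripts differ in the treated tissue. The treatment label of the normal group names normal feeding only, so effects of the procedure and of TNBS cannot be told apart here. Among the called genes, those that rose included genes of neutrophils, of the acute-phase response and of endothelium, and those that fell included genes of goblet cells, of absorptive colonocytes, of cell division and of the antiviral interferon response. Of 14126 genes tested with edgeR's quasi-likelihood test, 128 were higher and 161 lower in TNBS colon at a Benjamini-Hochberg adjusted p under 0.05, and 122 and 148 of these differed at least 2-fold. The values of the groups did not overlap for 4254 genes, 30.1% of those tested against 10% by chance, and for all 289 called genes. The 10% is an average over all splits of the libraries, and genes vary together, so this difference is not a test. DESeq2 called 666 higher and 679 lower, and limma-voom 80 and 146. The counts rest on each library: 38 higher and 45 lower genes were called without normal replicate 1, 7 and 11 without normal replicate 2, and 18 and 30 without normal replicate 3. There were 532 and 576 without TNBS replicate 1, 30 and 31 without TNBS replicate 2, and 43 and 51 without TNBS replicate 3. With TNBS replicate 2 as the only TNBS library, leaving out both that were low in Y-linked transcripts, 338 genes were higher and 480 lower. With TNBS replicate 1 as the only TNBS library, leaving out both whose Hox transcripts lay apart, 30 were higher and 33 lower. In both fits the lone library was assumed to vary like the normal ones.

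The title of the series names FTO, the demethylase that removes N6-methyladenosine (m6A) from RNA. Fto, with the identifier ENSMUSG00000055932, lies on chromosome 8 from 91313525 to 91668439 of the mm10 build. It was at 56.2 ± 4.10 CPM (SD, n = 3) in normal colon and at 57.8 ± 9.29 CPM (SD, n = 3) in TNBS colon. Its log2 fold change was 0.04 with a standard error of 0.18 (edgeR adjusted p = 0.918), and the 95% interval ran from a fold of 0.771 to a fold of 1.37. The exact two-sided permutation test of its 6 values gave p = 0.9, where the smallest p that 3 against 3 allows is 0.1. Without TNBS replicate 1 the sign turned, to -0.10, and without normal replicate 1 the value was -0.0026; Fto was past the threshold in none of the alternatives run. None of the 20 tested genes of the m6A list, which holds writers, erasers and readers of this mark, passed edgeR's test, and 0 did when adjusted over the list alone. Of these genes 2 were lower at an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom 0. The list's median log2 fold change was -0.11 (camera adjusted p = 0.203), and fry, which asks whether the genes of a list move one way on balance, gave an adjusted p of 0.0351 for a lower level. The member furthest from 0 was Igf2bp3, a reader, at 0.533 ± 0.463 CPM in normal and 1.37 ± 0.451 CPM in TNBS colon (SD, n = 3; adjusted p = 0.519).

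**Figure D1:**
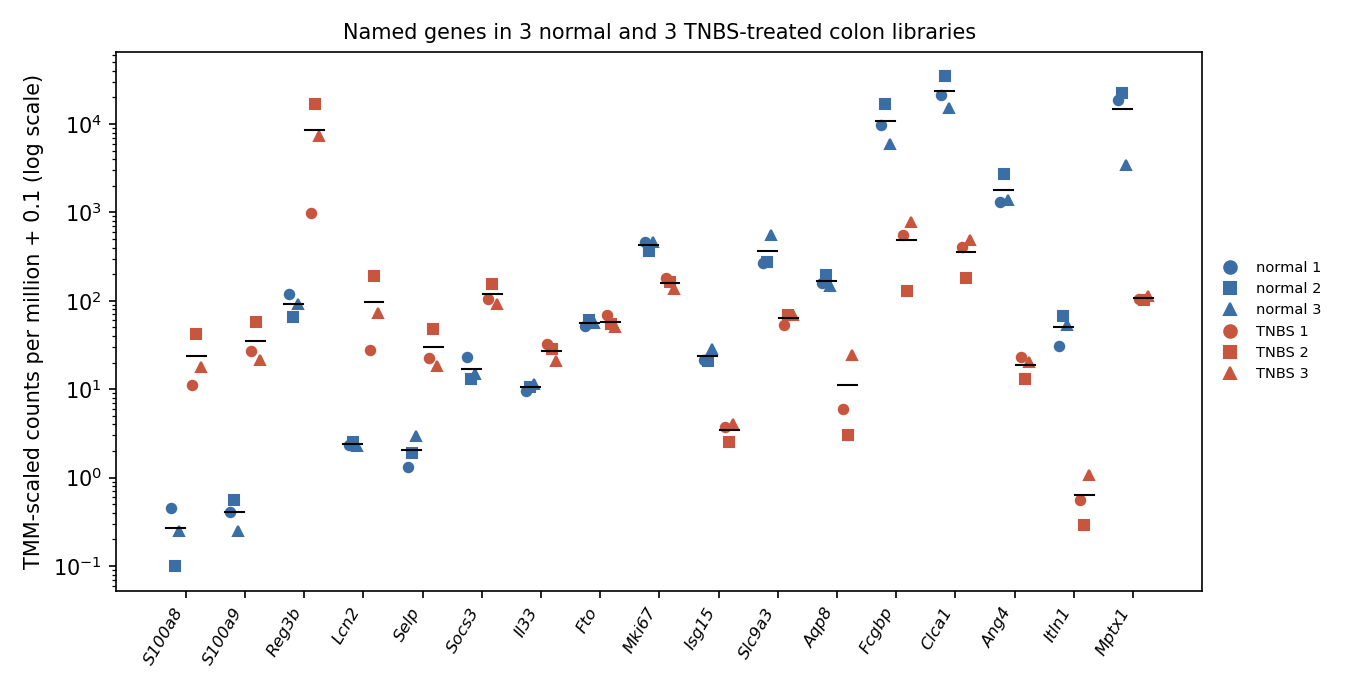
TMM-scaled CPM plus 0.1 on a log axis for 17 named genes, 1 point per library with the mean of each group as a bar, normal libraries in blue and TNBS libraries in red. S100a8 averaged 0.167 CPM in normal and 23.8 in TNBS colon, Ang4 averaged 1792 CPM in normal and 18.6 in TNBS colon, and the values of Fto overlapped.

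Neutrophil transcripts rose the most among the lists. Of 13 tested, 7 rose and none fell (11 rose when adjusted over the list alone), all 13 had a higher mean in TNBS colon, and the median log2 fold change was 3.63. S100a8 and S100a9, the subunits of the antimicrobial protein calprotectin, went from 0.167 ± 0.175 to 23.8 ± 16.5 CPM and from 0.303 ± 0.151 to 35.1 ± 19.1 CPM (SD, n = 3), log2 fold changes of 7.08 (SE 0.86, edgeR adjusted p = 0.0123) and 6.81 (SE 0.55, adjusted p = 0.00198). Both lie on chromosome 3, S100a8 from 90668978 to 90670035 and S100a9 from 90692632 to 90695721. Mmp8, the neutrophil collagenase, had 1 count in the normal libraries together and 253 in the TNBS libraries, a ratio of 288 with a 95% counting interval of 51.2 to 11412 (adjusted p = 0.0128). Cxcr2, the receptor for neutrophil-attracting chemokines, which was picked after its values were seen, rose by 4.70 on the log2 scale (SE 0.98, adjusted p = 0.0488). The list's camera adjusted p was 9.71e-13 with the preset correlation, and the adjusted p was 0.295 with an estimated correlation.

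The monocyte and macrophage list had 3 of 20 genes higher and none lower (4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0762). Chil3, a chitinase-like protein of alternatively activated macrophages that is also made by neutrophils, reached 3.68, 50.8 and 18.8 CPM in the TNBS libraries from 0.0505 to 0.227 in the normal ones, a log2 fold change of 7.40 (adjusted p = 0.0165). It shares 26.9% of its 50-base stretches with other transcripts, mainly Chil4, so its counts are uncertain. Fcgr3, an immunoglobulin Fc receptor, went from 19.4 ± 1.66 to 49.6 ± 2.36 CPM (SD, n = 3; adjusted p = 0.0156), and Cd14, the co-receptor for bacterial lipopolysaccharide, from 17.9 ± 1.66 to 40.8 ± 9.36 CPM (adjusted p = 0.0427).

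Of 14 cytokine genes 1 rose, 4 when adjusted over the list alone, and 13 had a higher mean in TNBS colon, with a median log2 fold change of 1.66 (camera adjusted p = 0.000218; adjusted p = 0.550 with an estimated correlation). The gene that passed was Il33, an alarmin released by damaged barrier tissue, which went from 10.4 ± 0.925 to 27.2 ± 5.79 CPM (SD, n = 3; adjusted p = 0.0333). Of 23 chemokine genes 1 rose, Cxcl2, with 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0800). Cxcl2, a neutrophil attractant, was at 19.5, 6.01 and 2.93 CPM in the TNBS libraries and at 0.0453 to 0.654 in the normal ones (log2 fold change 4.73, SE 0.96, adjusted p = 0.0451). The NF-kB and inflammasome list had 2 of 22 genes higher, 8 when adjusted over the list alone, and a median of 0.59 (camera adjusted p = 0.000218; adjusted p = 0.443 with an estimated correlation). These were Socs3, a feedback inhibitor of cytokine signalling, from 16.9 ± 5.32 to 118 ± 33.7 CPM (adjusted p = 0.00676), and Nfkbia, the inhibitor of NF-kB, from 76.0 ± 15.1 to 224 ± 87.0 CPM (adjusted p = 0.0368). Among the pathway annotations that the deposited table carries, TNF signaling held 7 of the called higher genes where 1.21 were expected, and NF-kappa B signaling 6 where 0.918 were expected, both with a hypergeometric adjusted p of 0.0385.

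Epithelial antimicrobial genes moved in both directions. Of 16 tested, 4 rose and 3 fell (5 and 5 when adjusted over the list alone). The median log2 fold change was -0.07 and the mean 0.35. Camera placed the list lower with an adjusted p of 0.770, and fry gave an adjusted p of 0.0361 for a lower level. Reg3b, a secreted C-type lectin that binds bacteria, was at 995, 16996 and 7325 CPM in the TNBS libraries against 92.1 ± 26.8 CPM in normal colon (SD, n = 3), a log2 fold change of 6.52 (SE 0.95, adjusted p = 0.0170). It lies on chromosome 6 from 78370657 to 78373466. Its neighbour Reg3a was at 1.27, 40.8 and 16.4 CPM in the TNBS libraries and at 0.105 ± 0.0983 CPM in normal colon (adjusted p = 0.0328). Lcn2, which sequesters bacterial siderophores, went from 2.28 ± 0.147 to 97.1 ± 84.0 CPM (adjusted p = 0.0123). The genes that fell included Ang4, an antimicrobial ribonuclease, and Itln1, a lectin that binds microbial glycans. Ang4 went from 1792 ± 774 to 18.6 ± 5.05 CPM (log2 fold change -6.58, SE 0.42, adjusted p = 0.00115), the smallest p of all genes, and Itln1 from 50.3 ± 18.5 to 0.541 ± 0.398 CPM (adjusted p = 0.00198). The acute-phase response annotation held 6 of the higher genes where 0.118 were expected (hypergeometric adjusted p = 8.20e-07): Hp, Reg3a, Reg3b, Reg3g, Saa3 and Serpina3n. Of the genes with the largest rises, Serpina3m, a serine protease inhibitor, went from 0.0633 ± 0.0326 to 6.42 ± 4.66 CPM (adjusted p = 0.0131), with 19.1% of its 50-base stretches shared with related genes. Fga, the fibrinogen alpha chain, had 2 counts in the normal libraries together and 211 in the TNBS libraries, a ratio of 120 with a 95% counting interval of 32.8 to 997 (adjusted p = 0.0295).

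Of 18 endothelial genes tested, 5 rose and none fell, 14 rose when adjusted over the list alone, and the median log2 fold change was 1.27 (camera adjusted p = 6.92e-07; adjusted p = 0.443 with an estimated correlation). Selp, the P-selectin on which leukocytes roll, went from 1.95 ± 0.812 to 29.7 ± 16.3 CPM (SD, n = 3; log2 fold change 3.92, SE 0.48, adjusted p = 0.0123). Ackr1, a chemokine-binding receptor of venules, went from 2.17 ± 0.0525 to 19.1 ± 14.3 CPM (adjusted p = 0.0344) and shares 20.4% of its 50-base stretches with the overlapping Cadm3. Cdh5, the cadherin of endothelial junctions, went from 26.4 ± 3.05 to 63.4 ± 17.1 CPM (adjusted p = 0.0360). In the extracellular matrix list 3 of 25 genes rose, 7 when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.0160; adjusted p = 0.727 with an estimated correlation). These included the proteases Mmp3, which went from 1.95 ± 0.941 to 33.3 ± 30.8 CPM (adjusted p = 0.0319), and Mmp10. Mmp10 went from 2.86 ± 0.902 to 23.4 ± 21.1 CPM (adjusted p = 0.0464). The collagen cross-linking enzyme Lox, the other gene that rose, went from 19.4 ± 5.95 to 57.7 ± 18.5 CPM (adjusted p = 0.0388). Mmp3 and Mmp10 share 8.39% and 8.37% of their 50-base stretches, mainly with each other. The median shift of the matrix list from the normal mean was 1.101 in TNBS replicate 1, -0.14 in TNBS replicate 2 and 0.37 in TNBS replicate 3. In the list of genes against oxidative stress and ferroptosis 2 of 20 rose, 5 when adjusted over the list alone (median 0.48; camera adjusted p = 0.0145; adjusted p = 0.514 with an estimated correlation). Hmox1, which degrades haem, went from 4.26 ± 1.34 to 14.2 ± 3.06 CPM (adjusted p = 0.0432), and Hp, which binds haemoglobin, from 0.662 ± 0.609 to 12.5 ± 6.28 CPM (adjusted p = 0.0440). Smooth muscle had 1 of 18 genes higher and 1 lower, 2 and 4 when adjusted over the list alone (camera adjusted p = 0.0883). The chaperone Hspb8 went from 25.9 ± 2.34 to 73.1 ± 11.7 CPM (adjusted p = 0.0128). The intermediate filament protein Synm went from 531 ± 153 to 143 ± 68.7 CPM (adjusted p = 0.0464).

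The largest falls were in genes of epithelial secretion and transport. Mptx1, a mucosal pentraxin on chromosome 1 from 174330518 to 174332873, went from 14788 ± 9992 to 107 ± 6.19 CPM (SD, n = 3; log2 fold change -7.11, SE 0.71, adjusted p = 0.00651). Its relative Mptx2, with which it shares 17.9% of its 50-base stretches, had 479 counts in the normal libraries together and 1 in the TNBS libraries, a ratio of 421 with a 95% counting interval of 75.2 to 16666 (adjusted p = 0.0328). Trpv6, an epithelial calcium channel, had 305 counts in the normal and 3 in the TNBS libraries, a ratio of 89.4 with a 95% counting interval of 30.3 to 436 (adjusted p = 0.0335). Tgm3, a transglutaminase, stood at 521, 107 and 30.4 CPM in the normal libraries and at 2.91 ± 1.73 CPM in TNBS colon (adjusted p = 0.0300). Pla2g4c, a phospholipase, went from 474 ± 258 to 7.04 ± 1.34 CPM (adjusted p = 0.00198). The Hox transcripts of TNBS replicates 2 and 3 lay apart from those of the normal libraries, as given above. The 28 called genes with a log2 fold change under -3 had a median shift from the normal mean of -4.13 in TNBS replicate 1, -4.34 in TNBS replicate 2 and -3.50 in TNBS replicate 3. These genes were chosen with all TNBS libraries included, so a fall in each was nearly fixed in advance.

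In the goblet cell list 3 of 18 genes fell and none rose, 7 fell when adjusted over the list alone, and the median log2 fold change was -0.87 (camera adjusted p = 1.21e-05; adjusted p = 0.555 with an estimated correlation). Clca1, a secreted mucus-processing protein on chromosome 3 from 145003817 to 145032776, went from 23735 ± 10114 to 357 ± 158 CPM (SD, n = 3; log2 fold change -6.06, SE 0.53, adjusted p = 0.00248). Fcgbp, a structural mucus protein, went from 10885 ± 5636 to 489 ± 330 CPM (adjusted p = 0.0207), and the mucin Muc3 from 3149 ± 469 to 937 ± 355 CPM (adjusted p = 0.0360). The gel-forming mucin Muc2 had a log2 fold change of -0.95 (SE 0.44, adjusted p = 0.255), and Spdef and Atoh1, transcription factors of the goblet cell lineage, 0.10 and -0.19 (adjusted p = 0.887 and 0.767); these 3 were picked after their values were seen. The median shift of the goblet list was -0.22 in TNBS replicate 1, -1.69 in TNBS replicate 2 and -1.12 in TNBS replicate 3. In the absorptive colonocyte list 4 of 20 genes fell, with 12 lower and 1 higher when adjusted over the list alone, and the median was -0.999 (camera adjusted p = 1.70e-05; adjusted p = 0.443 with an estimated correlation). Slc9a3, the apical sodium-proton exchanger, went from 366 ± 164 to 63.6 ± 9.01 CPM (adjusted p = 0.0123). The sodium channel subunit Scnn1a went from 126 ± 17.4 to 45.2 ± 10.2 CPM (adjusted p = 0.0165). The water channel Aqp8 went from 166 ± 26.2 to 10.9 ± 11.4 CPM (adjusted p = 0.0300). None of the 22 genes of the epithelial junction list passed, over all genes or adjusted over the list alone (median -0.15; camera adjusted p = 0.203). At an unadjusted p under 0.05 edgeR had 2 higher and 6 lower, DESeq2 called 1 and 1, and limma-voom 0. Its member furthest from 0, Tjp1, was at 2.51 ± 0.221 CPM in normal and 1.04 ± 0.591 CPM in TNBS colon (adjusted p = 0.301). Pan-epithelial genes, a set fixed after the data were first examined and before their values were seen, had log2 fold changes from -0.55 (Cdh17) to 0.82 (Lgals4), none past the threshold. The keratins Krt8 and Krt18 had log2 fold changes of -0.30 and -0.10 (SE 0.22 and 0.22, adjusted p = 0.446 and 0.826). Epcam was at -0.51 (SE 0.22, adjusted p = 0.229) and Lgals4 had a standard error of 0.32 (adjusted p = 0.195).

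Of the 20 genes of the stem cell and proliferation list 5 fell and none rose, 8 fell when adjusted over the list alone, and the median log2 fold change was -0.69 (camera adjusted p = 2.87e-06; adjusted p = 0.550 with an estimated correlation). Mki67 went from 432 ± 58.1 to 160 ± 23.1 CPM (SD, n = 3; adjusted p = 0.0156). The cyclin Ccna2 went from 122 ± 18.3 to 49.7 ± 7.49 CPM (adjusted p = 0.0175) and the topoisomerase Top2a went from 271 ± 77.6 to 97.1 ± 30.4 CPM (adjusted p = 0.0372). The other members that fell were Birc5 and Ccnb1. The stem cell marker Lgr5, picked after its values were seen, had a log2 fold change of -0.39 with a standard error of 0.93 (adjusted p = 0.836). Among the annotated processes, mitotic nuclear division held 12 of the lower genes where 2.57 were expected, and chromosome segregation 7 where 0.792 were expected, each with a hypergeometric adjusted p of 0.00274. The list's median shift was -0.35 in TNBS replicate 1, -1.18 in TNBS replicate 2 and -1.12 in TNBS replicate 3. No gene of the 21 of the unfolded protein response list passed edgeR's test or did so when adjusted over the list alone, while 8 were lower at an unadjusted p under 0.05, DESeq2 called 3 lower and limma-voom 0. The list's median was -0.62 (camera adjusted p = 0.00147; adjusted p = 0.550 with an estimated correlation), with the chaperone Hsp90b1 at 1762 ± 438 CPM in normal and 853 ± 294 CPM in TNBS colon (adjusted p = 0.113). The median shift of this list was -0.20 in TNBS replicate 1, -1.04 in TNBS replicate 2 and -0.66 in TNBS replicate 3, against -0.17 to 0.10 in the normal libraries.

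Of 28 interferon-induced genes tested, 10 fell and 1 rose, 13 fell and 2 rose when adjusted over the list alone, and the median log2 fold change was -0.77 (camera adjusted p = 0.000218; adjusted p = 0.577 with an estimated correlation). Isg15, a ubiquitin-like modifier, went from 23.5 ± 4.14 to 3.36 ± 0.796 CPM (SD, n = 3; log2 fold change -2.80, SE 0.30, adjusted p = 0.00698). Oasl2, of the oligoadenylate synthetase family, went from 393 ± 100 to 59.7 ± 25.8 CPM (adjusted p = 0.0128), and Usp18, which removes the Isg15 modifier, from 24.6 ± 8.86 to 4.48 ± 1.14 CPM (adjusted p = 0.0156). The member that rose was Iigp1, an interferon-gamma-induced GTPase outside the naming rule, with a log2 fold change of 1.83 (SE 0.32, adjusted p = 0.0328). The list's median shift was -0.91 in TNBS replicate 1, -0.98 in TNBS replicate 2 and -0.43 in TNBS replicate 3. The annotated defense response to virus held 10 of the lower genes where 0.781 were expected (hypergeometric adjusted p = 2.57e-06). The interferon-induced membrane proteins Ifitm1, Ifitm2 and Ifitm3 were among the higher genes, under the annotation response to virus, which held 4 of these where 0.280 were expected (adjusted p = 0.0216).

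Of the lymphoid lists, the 18 T and NK cell genes had a median log2 fold change of 1.06 (camera adjusted p = 0.00291; adjusted p = 0.555 with an estimated correlation). None passed edgeR's threshold and 3 were higher when adjusted over the list alone. Of these genes 8 were higher at an unadjusted p under 0.05, DESeq2 called 4 higher and limma-voom 0. Foxp3, the transcription factor of regulatory T cells, was at 0.234 ± 0.296 CPM in normal and 1.94 ± 0.488 CPM in TNBS colon (SD, n = 3; adjusted p = 0.183). All 17 B and plasma cell genes had a lower mean in TNBS colon, with a median of -1.64 (camera adjusted p = 0.0249; adjusted p = 0.727 with an estimated correlation). None passed edgeR's threshold and 2 were lower when adjusted over the list alone. Of these genes 5 were lower at an unadjusted p under 0.05, DESeq2 called 3 lower and limma-voom 0. The normal libraries differed most for these genes, with a median shift of 2.29 in normal replicate 1, 0.06 in normal replicate 2 and -2.13 in normal replicate 3, against -0.90 to -0.19 in the TNBS libraries. Cr2, a complement receptor of B cells, was at 6.59 ± 10.1 CPM in normal and 0.455 ± 0.418 CPM in TNBS colon (adjusted p = 0.224).

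The other cell type lists did not pass camera. The median log2 fold change was 0.37 for 16 fibroblast genes (camera adjusted p = 0.385), 1.0004 for 8 mast cell and eosinophil genes (0.867), 0.47 for 17 enteroendocrine and tuft cell genes (0.240), 0.49 for 7 skeletal muscle genes (0.540) and 2.10 for 5 erythroid genes (0.385). It was 0.02 for 20 genes of enteric neurons and glia, which camera placed lower (0.867), -0.09 for 12 genes of fat and mesothelium, whose mean was 0.15 and which camera placed higher (0.889), and -0.20 for 9 genes of squamous anal epithelium, which camera placed higher (0.867). No gene of these 8 lists passed edgeR's test over all genes, and adjusted over the list alone 1 erythroid gene was higher and none in the others. At an unadjusted p under 0.05, edgeR had 7 fibroblast, 1 mast cell, 4 enteroendocrine, 2 fat and 2 erythroid genes higher, 1 squamous gene higher and 1 lower, 2 enteric genes lower and 1 skeletal muscle gene lower. DESeq2 called 1 fibroblast, 2 enteroendocrine, 1 fat and 2 erythroid genes higher and 1 enteric gene lower, and limma-voom called 0. The members furthest from 0, none past the threshold, were Grem1 (log2 fold change 1.42), Mcpt1 (3.31), Insl5 (-2.29), Mylpf (1.75), Hbb-bs (3.004), Chat (1.88), Fabp4 (2.03) and Krt15 (2.62). Hbb-bs shares 53.2% of its 50-base stretches, mainly with Hbb-bt.

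Metabolic lists did not pass camera either. The median was 0.13 for 24 genes of fatty acid oxidation (camera adjusted p = 0.240), 0.15 for 25 genes of oxidative phosphorylation (0.240), 0.10 for 23 genes of hypoxia and glycolysis (0.857) and -0.21 for 26 genes of xenobiotic and bile metabolism, whose mean was 0.12 and which camera placed lower (0.366). In the last list 1 gene fell, with 4 higher and 2 lower when adjusted over the list alone: Cyp4f14, a cytochrome P450, from 120 ± 22.9 to 53.3 ± 10.4 CPM (SD, n = 3; edgeR adjusted p = 0.0360). In the others none passed edgeR's test, and adjusted over the list alone 1 hypoxia gene was higher. At an unadjusted p under 0.05, 5 oxidation genes were higher and 1 lower, 1 gene of oxidative phosphorylation was lower, and 2 hypoxia genes were higher and 3 lower. DESeq2 called 2 and 1, 0 and 0, and 1 and 1, in the same order, and limma-voom 0. The members furthest from 0 were Pdk4 (log2 fold change 2.50, adjusted p = 0.101), Ndufv1 (0.59, 0.276) and Pfkfb3 (1.65, 0.0595).

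**Figure D2:**
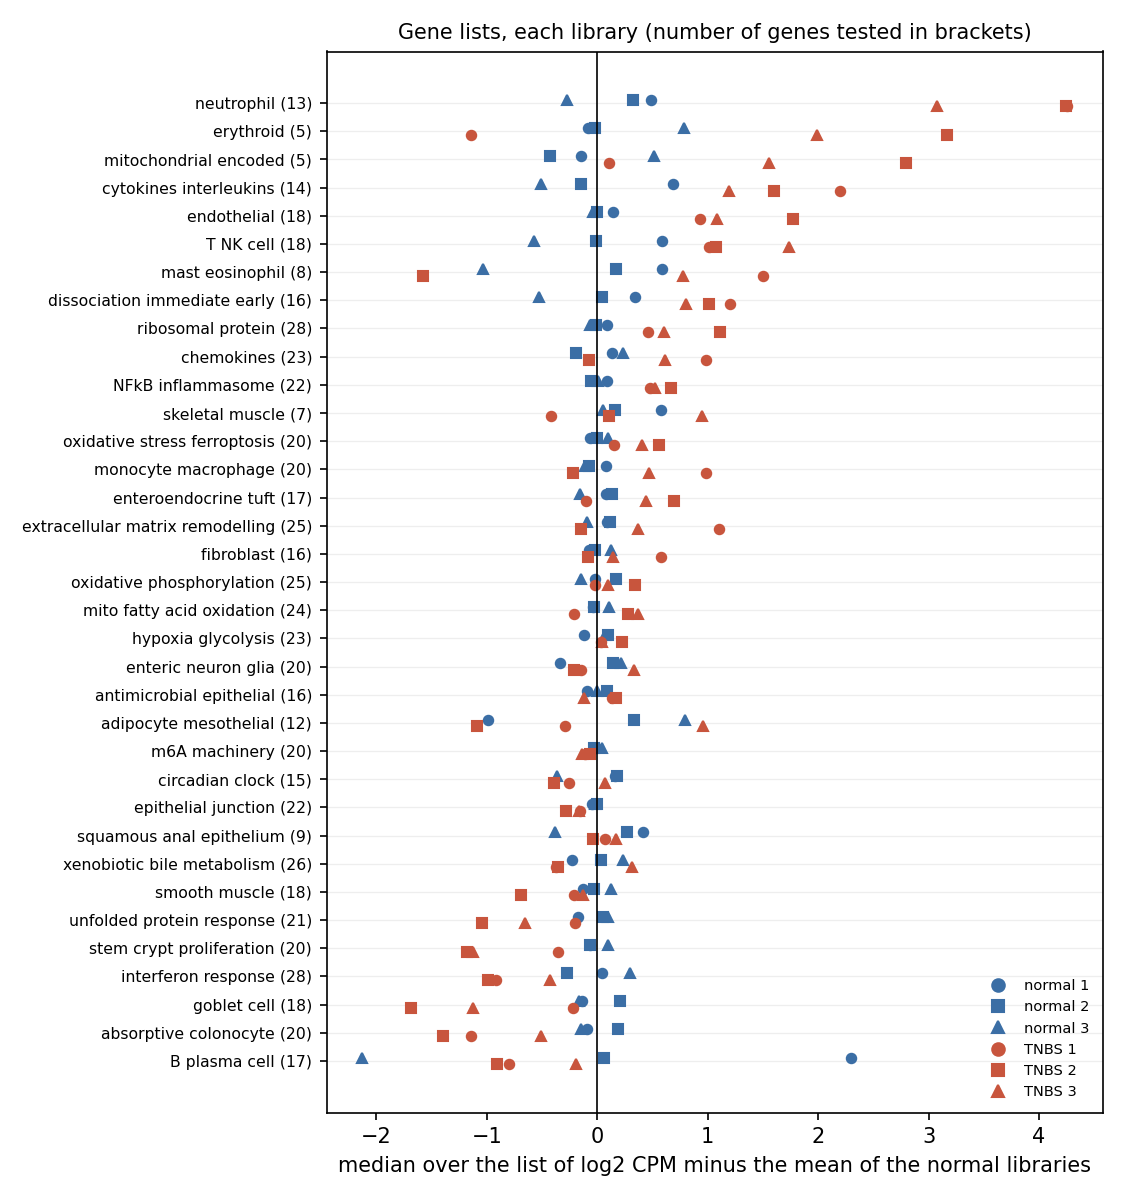
For each of the 35 gene lists, the median over its tested genes of log2 CPM minus the mean of the normal libraries, 1 point per library, normal in blue and TNBS in red. All TNBS libraries lie above the normal ones for the neutrophil list, at 4.25, 4.25 and 3.07, while the erythroid list separates TNBS replicate 1, at -1.14, from TNBS replicates 2 and 3, at 3.17 and 1.99.

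Of the 4 lists fixed to follow RNA quality and handling, the clock genes did not pass camera and the others did so with the preset correlation only. The immediate early genes had 1 of 16 higher, Ier3, with 11 higher and 2 lower when adjusted over the list alone (median 0.87; camera adjusted p = 0.00128; adjusted p = 0.550 with an estimated correlation). Ier3 went from 12.8 ± 4.67 to 45.1 ± 10.6 CPM (SD, n = 3; adjusted p = 0.0338). The 5 mitochondrially encoded genes had a median of 1.89 (camera adjusted p = 0.0266; adjusted p = 0.603 with an estimated correlation) and the 28 ribosomal protein genes 0.75 (camera adjusted p = 3.63e-09; adjusted p = 0.555 with an estimated correlation). No member of either passed edgeR's test over all genes, while 4 and 22 were higher when adjusted over the list alone and 4 and 23 at an unadjusted p under 0.05; DESeq2 called 3 and 18 higher and limma-voom 0 and 0. The mitochondrial median shift was 0.10 in TNBS replicate 1, inside the normal range of -0.43 to 0.52, 2.79 in TNBS replicate 2 and 1.56 in TNBS replicate 3. Rps19 was at 116 ± 41.2 CPM in normal and 270 ± 85.0 CPM in TNBS colon (adjusted p = 0.0916), and mt-Co3, of which 99.9% of the 50-base stretches recur in a nuclear copy, at 251 ± 94.4 and 1754 ± 1610 CPM (adjusted p = 0.103). None of the 15 clock genes passed edgeR's test, and 0 did when adjusted over the list alone. There were 1 higher and 2 lower at an unadjusted p under 0.05, 1 higher by DESeq2 and 0 by limma-voom (median -0.13; camera adjusted p = 0.512). Per1 was at 40.2 ± 19.9 and 90.3 ± 21.4 CPM (adjusted p = 0.143).

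**Figure D3:**
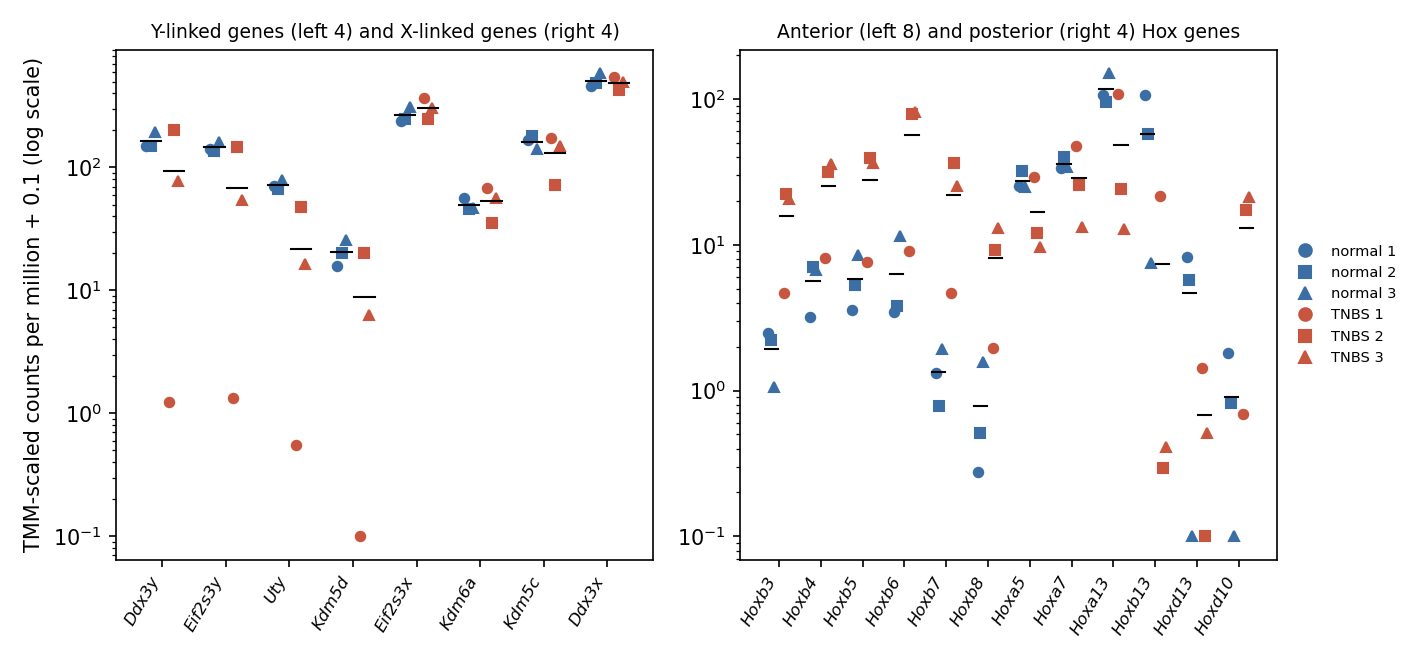
TMM-scaled CPM plus 0.1 on log axes, 1 point per library with the mean of each group as a bar. On the left, Y-linked genes fall near 0 in TNBS replicate 1 (Ddx3y 1.14 CPM, against 201 in TNBS replicate 2 and 78.0 in TNBS replicate 3), and on the right TNBS replicates 2 and 3 lie above the other libraries for Hoxb3 to Hoxb8.

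Of the named genes, 47 passed the threshold. None of these changed direction under any alternative. Their groups did not overlap, however, so leaving out libraries could hardly turn a direction. The number that stayed past the threshold was 23 without normal replicate 1, 11 without normal replicate 2, 15 without normal replicate 3, 46 without TNBS replicate 1, 23 without TNBS replicate 2 and 25 without TNBS replicate 3. It was 17 with TNBS replicate 1 as the only TNBS library, 37 with TNBS replicate 2 as the only one, 30 with limma-voom and 28 with limma-voom after quantile normalization.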

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

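The fits with the length and GC correction and the fits with TNBS replicate 1 or 2 as the only TNBS library were chosen after seeing the data. None of the 47 named genes past the threshold changed direction under any alternative. For fits with fewer libraries this was nearly fixed in advance, since the groups of these genes did not overlap. All 47 stayed past the threshold with DESeq2, with median-of-ratios scaling and without the filter on low counts. The counts of genes higher and lower were 209 and 210 without that filter, 159 and 170 at a mean count of at least 50, 129 and 168 with median-of-ratios scaling, 95 and 144 after quantile normalization, 80 and 146 with limma-voom, and 666 and 679 with DESeq2. They were 1151 and 1265 with quality weights, 142 and 222 with the length and GC correction, 615 and 845 with that correction and no TNBS replicate 1, 338 and 480 with TNBS replicate 2 as the only TNBS library, and 30 and 33 with TNBS replicate 1 as the only one. Leaving out 1 library at a time gave 7 to 532 higher and 11 to 576 lower genes. A block for the replicate number gave 153 and 207, but the numbers do not pair the libraries: deviations of libraries with the same number correlated at 0.00547, 0.0149 and 0.0354. Lists called higher and lower were 0 and 0 by camera with an estimated correlation, 4 and 3 by fry, and 10 to 12 and 5 to 8 when 1 library was left out. The log2 fold change of Fto was -0.11 with quality weights, -0.050 with TNBS replicate 2 alone, 0.28 with TNBS replicate 1 alone, 0.16 with the length and GC correction, and -0.10 to 0.13 when 1 library was left out, past the threshold in none. These list medians turned in sign: without the filter, antimicrobial 0.048 and squamous 0.32; at a mean count of at least 50, antimicrobial 0.059 and squamous 0.27. They were, after quantile normalization, enteric -0.091; with limma-voom, squamous 0.25; with quality weights, oxidative phosphorylation -0.0014 and fat 0.63; with the replicate block, squamous 0.25. With the length and GC correction they were oxidative phosphorylation -0.031, hypoxia -0.12, enteric -0.24 and skeletal muscle -0.00054. With TNBS replicate 2 alone, Mcpt1 was at -6.13, and the list medians were chemokines -0.25, monocytes -0.48, mast cells -5.44, antimicrobial 0.36, matrix -0.17, fibroblasts -0.10 and enteric -0.24. With TNBS replicate 1 alone, Pdk4 was at -0.27, Chat at -0.19 and mt-Co3 at -0.16, and the medians were antimicrobial 0.068, enteroendocrine -0.12, fatty acid oxidation -0.21, oxidative phosphorylation -0.054, hypoxia -0.015, enteric -0.18, skeletal muscle -0.27 and erythroid -1.95. When 1 library was left out, medians ran from -0.29 to 0.20 (antimicrobial), -0.13 to 0.11 (enteric), -0.15 to 0.11 (squamous), -0.33 to 0.024 (clock), -0.36 to 0.34 (fat), -0.025 to 0.76 (monocytes) and -0.013 to 0.17 (hypoxia). Fewer libraries or genes are part of how the left-out and filtered fits were made; otherwise the cause was not tested. Other pseudocounts and limma on normalized values were not run, since counts were used, and neither was a limit to protein-coding genes, since every gene of the table is one. Depth limits genes near 3 counts, which is 0.128 to 0.198 CPM.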

Other observations

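Chosen only after the result was seen were all tests of the Y-linked transcripts and the test of colon position in TNBS replicate 1 alone; the other tests below were fixed before their results were seen. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many calls (289), and the highest of the others gave 0; 10 splits are too few to decide.

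Y-linked transcripts were near 0 in TNBS replicate 1 and lower in TNBS replicate 3, although the labels name males. A fall shared by the TNBS colons is argued against by TNBS replicate 2, at 1.03 times the normal mean. Tissue from a female animal may account for TNBS replicate 1, where 4 genes that escape X inactivation were at a median of 1.73 times their level in TNBS replicate 2. That reference was itself low, since Kdm6a, Kdm5c and Ddx3x lay below the normal range in TNBS replicate 2. Against the normal libraries, only Eif2s3x and Kdm6a of these genes lay above the range in TNBS replicate 1. A mix of TNBS replicates 1 and 2 as the origin of TNBS replicate 3 stays open. The share of each was set by the Y-linked genes. Of 300 genes at least 4-fold apart, 46.3% (95% interval 40.6 to 52.2) lay within 1.5-fold of the mixed level. An earlier test, replaced after its result, found 87.3% (83.0 to 90.9) between both libraries, with a tolerance of 10%. It decides nothing, since genes chosen as far apart in both libraries leave a wide range that an unrelated library could also fall into. Both intervals treat genes as independent. Against a mix, 173 of all 14126 tested genes lay over 1.5 times above both libraries in TNBS replicate 3, at 10 CPM or more there. A further 47, at 10 CPM or more in both libraries, lay over 1.5 times below both. These are small shares of the genes, and the variation between preparations of the same RNA was not measured. Were TNBS replicate 3 such a mix, the TNBS libraries would not be independent, and the p-values given above would be too small.

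The 28 called genes with a log2 fold change under -3 had a median of -3.93. A lower total share of epithelial cells is argued against by 10 pan-epithelial genes, at a median of -0.18. These genes cannot show a shift between epithelial cell types, which was not tested. A length or GC trend as the whole cause is argued against too. The median of the 28 genes kept 0.9998 of its size after the correction. A different position along the colon could contribute in TNBS replicates 2 and 3. The median log2 fold change of the posterior Hox genes minus that of the anterior ones was -4.79. The standard error of 1.75 over genes is that of a difference of means and does not measure the spread of this value. Hoxd10 moved against the other posterior genes, at a log2 fold change of 3.97. Hoxa5 and Hoxa7, at -0.71 and -0.31, moved against the other anterior genes, which are all of the Hoxb cluster. In TNBS replicate 1 the posterior minus anterior Hox difference was -0.84, inside the wide normal range of -2.81 to 2.03. The falls there had a median of -4.13, but these genes were called with that library included. Position as their cause in that library is therefore not decided. TNBS itself stays open.

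Leaving out TNBS replicate 1 raised the calls from 289 to 1108. A length or GC trend is argued against as the cause, since after the correction the calls still rose by 4.01 times. A milder median rise of the neutrophil and cytokine lists in TNBS replicate 1 is argued against too. Its neutrophil shift was 1.16 times and its cytokine shift 1.57 times the mean of the other TNBS libraries. Milder inflammation in other respects stays open, since named genes differed in direction. Reg3b was at 995 CPM in TNBS replicate 1 against 16996 and 7325 in TNBS replicates 2 and 3, and Lcn2 at 27.7 against 191 and 73.0. Cxcl2 went the other way, at 19.5 against 6.01 and 2.93 CPM. In TNBS replicate 1 alone, 128 of 128 higher and 161 of 161 lower calls kept their direction, but these genes were called with that library included. Whether its Hox or Y-linked differences may be the cause was not tested.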
